A study of Mus musculus with 18 samples.

How the data were processed

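CUT&RUN libraries were made from mouse splenic NK cells that had been purified by sorting or with a magnetic kit, expanded for 5 to 7 days in IL-15 at 5 ng/ml and rested without it for 1 hour. Per the labels, cells were stimulated with IL-12 at 20 ng/ml for 15 minutes or left unstimulated, and for CDK9 this was followed by IL-18 at 10 ng/ml for 15 minutes while the other CDK9 conditions received medium. Sorted cells, 500k per library and 300k for CDK9, were incubated with 1 of 4 antibodies, and yeast DNA was added as a spike-in. Sequencing was paired-end with 100 bases, on average 18M reads per sample according to the labels. The depth of single libraries and any use of the spike-in were not used here, because the tables hold neither.

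The authors deposited 1 table of regions per antibody, whose values are in no count, coverage or normalised unit but in another unit, a peak call of 1 or 0 for each library, with the number of libraries called and a group call (2 or more libraries) beside it. Each region has a position, a type (promoter, exon, intron or intergenic) and a gene. Per the submitters' processing notes, Trimmomatic 0.39, Bowtie2 2.4.1, MACS2 2.2.7.1, DESeq2 1.46.0 and deepTools 3.5.2 were used on genome build mm10, with no roles or thresholds given. Checked on the values, the NELFE, CDK9 and STAT4 tables list only regions with a group call in at least 1 group, so a region's presence depends on its calls. The DDX5 table also lists 95 regions without one, of which 73 have 1 call and 8 none. Gene IDs were matched to the RefSeq gene table of the same assembly for all DDX5 and NELFE regions, 11198 of 11202 CDK9 regions and 24137 of 24144 STAT4 regions.

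Libraries were grouped by the antibody, condition and replicate that the labels give. The comparisons, their samples, 16 gene lists, 30 named genes, alternatives and the threshold of 0.05 were chosen before the data were examined. That plan used a negative binomial model of peak counts with a batch term for DDX5, and camera for gene lists. Calls allow neither, so both were replaced after the unit was seen, and the rule for naming genes with them. Instead, a region was taken as called in 1 group only when every library of it and none of the other had a call. Numbers of calls per library were compared by exact two-sided permutation of the libraries, with and without the batches of DDX5. For gene lists with at least 5 regions, the mean difference in the share of libraries with a call was compared with 100000 random lists of genes with as many regions per gene, by a two-sided permutation test across genes, with Benjamini-Hochberg adjustment over the lists of a comparison. Regions with and without an overlapping STAT4 region (1 base or more) were compared by an exact two-sided test over all circular shifts of the differences along the genome. Tests across genes or regions describe these libraries and not replicate cells. Overlap percentages were set against 100 shuffles of positions within chromosomes.

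The genes named are, for each comparison and direction, from the 10 with the most regions called in 1 group only (ties by total width), the 30 genes fixed in advance, and members of the lists, and for STAT4 the 10 genes with the widest region. Genes with the most STAT4 regions are named beside them. The lists cover cytokines and chemokines, JAK-STAT signalling and feedback, IL-18 and NF-kB signalling, immediate early genes, NK cytotoxicity and receptors, lymphocyte transcription factors, interferon-stimulated genes, polymerase pausing and elongation, replication-dependent histones, ribosomal proteins, glycolysis and nutrient uptake, cell cycle, and markers of T cells, B cells, myeloid cells, and erythroid cells with platelets. To set the counts of the IL-18 step against chance in spite of the selection in the table, regions were taken that both unstimulated CDK9 libraries called. The other CDK9 comparisons have no such group, because the group outside each also received IL-12.

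The procedure was tested on simulated data made from the CDK9 table. Of 200 regions given a change, 81.0% were called in 1 group only, against 81.5% computed from the rates, and 2.86% of unchanged regions were. Of 200 random gene lists 3.0%, and of 200 null shift tests 7.5%, had an unadjusted p below the threshold. The simulated calls were independent between regions and were not selected by group calls. These rates therefore need not hold for the real regions. Alternatives were leaving out each library, the replicate number as a block, each DDX5 batch alone, the group call, promoter regions alone, the widest region per gene, width-matched random lists, Fisher's exact test and stricter overlaps. Alternatives that need counts were not run. A withheld item is not reported here. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used, with a fixed seed.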

Results

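Binding of 4 proteins to chromatin was mapped by CUT&RUN, in which an antibody directs a nuclease to cut the DNA around its target, in cultured mouse splenic NK cells with and without IL-12. The antibodies were against STAT4, the transcription factor that IL-12 activates, DDX5, an RNA helicase, NELFE, a subunit of the NELF complex that holds paused RNA polymerase II, and CDK9, the kinase of P-TEFb that releases it. Of 18 libraries, DDX5 had 3 unstimulated and 3 IL-12, NELFE 2 and 2, CDK9 2 unstimulated, 2 IL-12 and 2 with IL-18 after IL-12, and STAT4 2 IL-12. Each antibody has 1 table of regions (mm10) with a peak call, present or absent, per library, and no counts or depths per library, so the depth behind each call is unknown. The tables hold 593 regions for DDX5 (median width 425 bp), 7212 for NELFE (704 bp), 11202 for CDK9 (534 bp) and 24144 for STAT4 (747 bp). Promoters made up 46.7%, 54.4%, 43.5% and 28.5% of them in that order. A region is named "IL-12-only" where it was called in every IL-12 library and no unstimulated one, and "unstimulated-only" in the reverse case. These are calls, not amounts of bound protein, and a gene's regions are those that the tables assign to it. Nothing says that replicates came from separate animals, so the p-values across libraries measure only the spread between these samples, which may be technical.

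The widest STAT4 regions after IL-12 lay at Ccr2, a chemokine receptor gene (17515 bp), Nabp1 (17018 bp), Park7 (15774 bp), Pim1, a kinase gene induced by cytokines (14394 bp), Bhlhe40, a lymphocyte transcription factor gene (14140 bp), Stk17b (13609 bp), Coro2a (12985 bp), Junb, an AP-1 gene (12916 bp), Gzma, which encodes a granzyme (12879 bp), and Gadd45g, a stress and cytokine response gene (12692 bp). The largest numbers of STAT4 regions were at Gm20388 (55), Gm17746 (33) and Pik3r1 (32). Of the genes fixed in advance, Tnfaip3, an inhibitor of NF-kB signalling, had 18 STAT4 regions. Ifng (gene ID 15978), which encodes the cytokine IFN-gamma, had 16. Nfkb1 had 12, and Il12rb2, the gene of the IL-12 receptor's beta 2 chain, had 9. Others had few, with 1 each at Junb, Ddx5 and Cdk9 and 0 at Nelfe. Among the gene lists, lymphocyte transcription factors had 7.85 STAT4 regions per gene, immediate early genes 5.21, JAK-STAT genes 5.03, cytokines and chemokines 4.81, IL-18 and NF-kB genes 4.17 and NK cytotoxicity genes and receptors 3.88, against 2.32 over all genes, each counted over the genes with a region and without a test. Interferon-stimulated genes had 1.87. Of the marker lists of other cells, 7 of 17 T-cell genes had a STAT4 region, with 4.29 per gene, and 5 of 16 B-cell, 10 of 24 myeloid and 1 of 13 erythroid genes had a STAT4 region. There is no unstimulated STAT4 library, and the table lists only regions called in both libraries, so these values have no background measured in the same way.

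DDX5 after IL-12, compared with unstimulated cells, asks whether the cytokine brings this helicase to chromatin. DDX5 had 66 IL-12-only regions, assigned to 64 genes, and 0 unstimulated-only regions. Cish, a feedback inhibitor of cytokine signalling, was IL-12-only at its promoter (chr9:107296337-107296809), as was Ifngr1, a chain of the IFN-gamma receptor (chr10:19591527-19591951). Nkg7, a cytotoxic granule gene, was IL-12-only (chr7:43436797-43437164), and so was an intergenic region 30.5 kb from Xcl1, a chemokine gene (chr1:164966048-164966457). Tex14 and Ppp1r3b, a regulator of glycogen metabolism, had 2 IL-12-only regions each. Further IL-12-only regions lay at the linker histone gene Hist1h1c, the histone H3 gene Hist2h3c2, the MAX-binding repressor gene Mnt, the costimulatory receptor gene Tnfrsf9 (4-1BB), the polymerase subunit gene Polr2e, Hnrnpul1, the ubiquitin gene Ubb and Rdm1. The Tnfrsf9 region (chr4:150924070-150925010) lay within the wide STAT4 region assigned to Park7 (chr4:150913181-150928954). Of 12 genes among 30 fixed in advance that had a DDX5 region, Cish and Xcl1 had an IL-12-only region, and the Ifng promoter region (chr10:118440615-118440935) was called in 1 of 3 IL-12 libraries and 0 of 3 unstimulated libraries.

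DDX5 calls numbered 354, 372 and 478 in the IL-12 libraries (401 ± 67.0, SD, n = 3) and 87, 133 and 192 in the unstimulated ones (137 ± 52.6, SD, n = 3), a ratio of 2.92. The exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries allow. Of the 162 regions called in exactly 3 of the 6 libraries, 40.7% were IL-12-only. Libraries with equal rates of calls would give 5% by chance, and the rates of these libraries alone give 38.3%, so this share restates the difference in calls per library. Promoters held 36 of the 66. Replication-dependent histone genes had 5 IL-12-only regions of 14, with a mean difference of 69.0 percentage points in the share of libraries with a call against 46.9 in random lists (two-sided permutation p across genes = 0.0239, adjusted p = 0.167 over 7 lists). JAK-STAT genes had 3 IL-12-only regions of 11, and none of the 7 lists tested passed. The libraries came in 2 batches. Batch 1, with 1 IL-12 and 2 unstimulated libraries, gave 234 regions called only after IL-12 and 13 only without it, and batch 2, with 2 and 1, gave 178 and 5. The libraries' own rates give 234 and 7.86 in batch 1 and 203 and 13.9 in batch 2. The split of the libraries by batch separated 71 regions, 30 called only in batch 1 and 41 only in batch 2, against 66 and 0 for the split by treatment, and the mean difference in calls was 264 pooled and 238.5 with batch taken into account (exact two-sided within-batch permutation p = 0.111, the smallest possible). Leaving out a library raises such counts by construction, here to 166 IL-12-only regions without IL-12 replicate 1, 131 without IL-12 replicate 2 and 119 without unstimulated replicate 3, the last with 12 unstimulated-only regions.

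NELFE after IL-12, compared with unstimulated cells, asks where the pausing factor stands after the cytokine. NELFE had 4056 IL-12-only regions in 3168 genes, which is 56.2% of all NELFE regions, and 1 unstimulated-only region, at Mir101c. At Ifng, 6 of 8 NELFE regions were IL-12-only. They were the promoter (chr10:118440295-118441686), regions 33.4, 27.7 and 21.3 kb on the low-coordinate side of the gene, and regions 23.1 and 40.7 kb on the high-coordinate side. The feedback inhibitor genes Socs1, with 7 of 8 regions, Socs3, with 3 of 3, and Cish, with 2 of 2, were IL-12-only at most or all of theirs. So were the IL-18 receptor genes Il18r1 (5 of 5) and Il18rap (2 of 2), Il12rb2 (2 of 2), Xcl1 (2 of 2) and Pim1 (3 of 4). The 27 genes fixed in advance that had a NELFE region held 49 IL-12-only regions of 70 together. Among them, Nfkb1 (1 of 5), Gzmb and Junb (1 of 3 each), and Tbx21, Ccl3 and Tnfaip3 (1 of 2 each) lay below the 56.2% of all regions.

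The largest numbers of IL-12-only NELFE regions were at Gm17746 (9 of 13), Morrbid, a long noncoding RNA gene that restrains the apoptosis gene Bcl2l11 (8 of 11), 4930459C07Rik (7 of 8), Klhl25 (7 of 10), the chromatin remodeller gene Chd7 (7 of 9), Prex1 (7 of 15, and 12 without unstimulated replicate 2), Mir704 (7 of 8) and Fam49b (6 of 7). The single regions of Nfkbia and Bcl3, both of the NF-kB pathway, were not IL-12-only, and the promoters of Ddx5 and Cdk9 were called in every NELFE library. Of 13 lists tested, 1 passed. Replication-dependent histone genes had 8 IL-12-only regions of 43 and a mean difference of 20.9 points against 69.9 in random lists (two-sided permutation p across genes = 1e-05, the smallest that 100000 draws give, adjusted p = 0.00013), and 76.7% and 81.4% of their regions were called in the unstimulated libraries. Both IL-12 libraries called 99.9% of all NELFE regions and 100% of the regions of each list tested. The list test therefore compares only calls without IL-12, where histone regions were called more often, and cannot show where NELFE rises after IL-12. JAK-STAT genes had 41 IL-12-only regions of 58 (adjusted p = 0.416), cytokines and chemokines 21 of 33 (adjusted p = 0.613) and interferon-stimulated genes 8 of 12, and none of these passed. Immediate early genes lay below random lists, with 40 of 84 (-10.9 points, adjusted permutation p = 0.242). They passed on promoters alone (-20.9 points, adjusted permutation p = 0.0102), and JAK-STAT genes passed with width-matched random lists (13.0 points, adjusted permutation p = 0.0379). The IL-12 libraries had 7207 and 7206 calls and the unstimulated ones 1314 and 3024 (2169 ± 1209, SD, n = 2), a ratio of 3.32 with an exact two-sided permutation p of 0.333, the smallest that 2 against 2 allow. Chance gives 16.7% of the 4057 regions called in exactly 2 of the 4 libraries in each direction, but the table lists only regions called in both libraries of a group, which by itself leaves out every mixed pair. The share of IL-12-only regions was 86.4% in the narrowest 10% of NELFE regions and 14.1% in the widest.

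CDK9 after IL-12, compared with unstimulated cells, asks where the elongation kinase goes after the cytokine. CDK9 had 884 IL-12-only regions in 732 genes and 1625 unstimulated-only regions in 1434 genes. Interferon-stimulated genes gained calls as a group, with 12 IL-12-only and 2 unstimulated-only regions of 34. The IL-12-only ones included the guanylate-binding protein genes Gbp2 (chr3:142619796-142620811), Gbp4, Gbp5 and Gbp7, the immunity-related GTPase genes Irgm1 (chr11:48871033-48871905), Irgm2 and Igtp, and Ifit3, Ifi203, Dtx3l and Trim30a, and the unstimulated-only ones lay at the RNA sensor gene Ddx58 and the antiviral gene Rsad2. Genes of JAK-STAT signalling and its feedback also gained calls, with 19 IL-12-only and 2 unstimulated-only regions of 82. Socs1 had 3 IL-12-only regions of 6, the phosphatase gene Ptpn1 3 of 5, the repressor gene Bcl6 2 of 4, Pim1 2 of 6, and Socs2 1 of 1.

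At Ifng, CDK9 was IL-12-only at 2 of 7 regions, 33.5 kb on the low-coordinate side (chr10:118406885-118407528) and 40.7 kb on the high-coordinate side (chr10:118486567-118487208), while its promoter was called in every CDK9 library. The largest numbers of IL-12-only regions were at Pvt1, a long noncoding RNA gene beside Myc (6 of 13), 9130015A21Rik (5 of 8), Lpp (5 of 12, with 2 unstimulated-only), the Src family kinase gene Fyn (5 of 8), Mgat4a, Iqgap2 and the kinase gene Mapkapk2 (4 of 5 each), and Gadd45g (3 of 9). The largest numbers of unstimulated-only regions were at Dusp2, a MAP kinase phosphatase gene (5 of 6), Gas7 (5 of 11), the PI3K adaptor gene Pik3ap1 (4 of 10), Acot7 (4 of 5), Bcr (4 of 4), Impa2 (3 of 3) and Zfp395 (3 of 4). Of the genes fixed in advance, Bcl3 had 2 IL-12-only regions of 3, Il18r1 2 of 6, Nfkb1 2 of 7 and Irf8, a transcription factor gene, 1 of 1, and Tnfaip3 had 1 unstimulated-only region of 7. Cish, Ccl3, Egr1, Nfkbia, Nr4a1 and Irf1 were called in every CDK9 library at all of their regions. Promoters were IL-12-only in 2.36% and unstimulated-only in 12.9% of cases, introns in 11.3% and 17.9%, and intergenic regions in 13.4% and 13.1%.

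The interferon list's mean difference was 33.8 points against -14.2 in random lists, and the JAK-STAT list's 22.0 points against -4.68 (adjusted p = 0.00013 and 0.00156 over 13 lists, two-sided permutation across genes, which describes these libraries). Other lists did not pass, among them lymphocyte transcription factors (26 IL-12-only and 14 unstimulated-only of 153, adjusted p = 0.118), cytokines and chemokines (7 and 1 of 51, adjusted p = 0.26) and NK cytotoxicity genes and receptors (5 and 6, adjusted p = 0.382). Lymphocyte transcription factors did pass with 1 region per gene (adjusted permutation p = 0.0484) and with Fisher's exact test (adjusted p = 0.000844). Histones passed with width-matched random lists (adjusted permutation p = 0.00312). Both unstimulated libraries called 100% of the histone regions, so their calls could only stay or fall. Calls numbered 8463 and 8375 after IL-12 (8419 ± 62.2, SD, n = 2) and 9760 and 9628 without (9694 ± 93.3, SD, n = 2). The exact two-sided permutation p was 0.333, the smallest possible. Regions called in only 1 library are not listed, so these SDs may understate the spread between libraries. Chance gives 16.7% of the regions called in exactly 2 of the 4 libraries in each direction where rates are equal, but the selection of regions by group calls leaves no valid comparison with it. Without IL-12 replicate 1 the unstimulated-only regions numbered 2492. The unstimulated-only share was 44.4% in the narrowest 10% of CDK9 regions and 0.624% in the widest, and the IL-12-only share 5.62% and 3.48%.

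CDK9 after IL-12 followed by IL-18, compared with unstimulated cells, asks the same of the combined stimulus. It had 757 regions called in both stimulated libraries only, in 650 genes, and 1759 unstimulated-only regions, in 1538 genes. Interferon-stimulated genes gained calls (13 stimulated-only and 2 unstimulated-only of 34), as did JAK-STAT genes (19 and 5 of 82). Cytokine and chemokine genes gained calls, with 9 and 1 of 51, among them Ifng, at the same pair of distal regions as after IL-12 alone, Csf2, which encodes GM-CSF, Ccl5, Fasl, the death ligand gene, and Tnfsf14, which encodes LIGHT (2). Genes of IL-18 and NF-kB signalling also differed from random lists, with 11 and 7 of 87, among them Nfkbiz, an atypical inhibitor of NF-kB (2 stimulated-only regions, 1 of them chr16:55808255-55810573), Bcl3 and the adhesion gene Icam1. After IL-12 alone the list had nearly the same counts, 10 and 6, and did not pass (adjusted permutation p = 0.374). Replication-dependent histone genes had fewer calls (0 and 8 of 36), among them Hist1h3h, Hist1h4m and Hist1h2be. Both unstimulated libraries called 100% of these histone regions, against a mean of 86.5% of all CDK9 regions. Histone calls could therefore only stay or fall, and the list test cannot separate this starting point from a loss particular to histones. The histone counts after IL-12 alone were the same, 0 and 8, with a mean difference of -30.6 points (adjusted permutation p = 0.257).

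The largest numbers of stimulated-only regions were at Gadd45g (4 of 9), Lpp (4 of 12, with 2 unstimulated-only), Snx29 (4 of 13), the Ras activator gene Rasgrp1 (3 of 6, with 1 unstimulated-only), Ptpn1 (3 of 5), Socs1 (3 of 6) and Ccn5 (3 of 3), and of unstimulated-only regions at Gas7 (5 of 11), Pik3ap1, Arhgap26, Lrrfip1, Syne3, Acot7 and Spice1 (4 each, and 8 for Pik3ap1 without IL-12 plus IL-18 replicate 2) and the CD45 gene Ptprc (3 of 6). Arhgap26 and Syne3 also had 1 stimulated-only region each. Il12rb2 had 1 stimulated-only and 3 unstimulated-only regions of 6. Mean differences were 33.8 points against -17.2 in random lists for interferon-stimulated genes, 21.3 against -8.71 for JAK-STAT, 17.6 against -7.79 for cytokines, 8.05 against -8.93 for IL-18 and NF-kB, and -37.5 against -18.7 for histones. Their adjusted p-values over 13 lists were 0.00013, 0.00013, 0.0209, 0.0426 and 0.0464 (two-sided permutation across genes). The call was lost for cytokines on promoters alone (adjusted p = 0.0789) and with the widest region per gene (0.529), for the IL-18 and NF-kB list with random lists matched on width (0.0895) and with Fisher's exact test (0.0922), and for histones on promoters alone (0.0517) and with Fisher's exact test (0.25). Without IL-12 plus IL-18 replicate 1 none of these 3 lists passed (adjusted p = 0.0541, 0.106 and 0.106), without unstimulated replicate 2 the IL-18 and NF-kB and the histone list did not (0.0642 each), and without IL-12 plus IL-18 replicate 2 the histone list did not (0.0606). Calls numbered 7199 and 8908 (8053.5 ± 1208, SD, n = 2) against 9694 ± 93.3, with an exact two-sided permutation p of 0.333, the smallest possible. The chance share of 16.7% per direction is subject to the same selection, and without IL-12 plus IL-18 replicate 2 there were 3430 unstimulated-only regions. The same unstimulated libraries serve both comparisons, so their shared regions, 498 stimulated-only and 998 unstimulated-only in both, are in part shared by construction. Simulated libraries with no effect and the same shared controls gave means of 35.3 (highest 52) and 165 (highest 198). The selection of regions by group calls also bears on the observed counts, so no conclusion on a shared response is drawn from this contrast.

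The IL-18 step compares CDK9 after IL-12 and IL-18 with CDK9 after IL-12 alone, which was given medium in place of IL-18 for the same time. It had 383 regions called only with IL-18, in 360 genes, and 454 called only without it, in 432 genes. Immediate early genes, which respond to a stimulus without new protein synthesis, gained calls, with 11 regions called only with IL-18 and 1 called only without it of 138. They included the antiproliferative gene Btg2 (2 of 5), Dusp1, a MAP kinase phosphatase gene (2 of 4), Ier5 (2 of 2, at chr1:155097873-155098474 and chr1:155099386-155099803), Dusp2, Egr3, Ier2 and the survival gene Mcl1. Of these 11 regions, 6 were called in both unstimulated libraries as well, among them the Dusp2 promoter and both Ier5 regions. Against unstimulated cells the list had 9 IL-12-only and 18 unstimulated-only regions after IL-12 (adjusted p = 0.391) and 11 and 9 after both cytokines (-3.62 points, adjusted p = 0.585), neither of which passed. Tnfsf14 was called only with IL-18 at 3 of 3 regions, and Nfkbiz (2 of 6), Tnfaip3 (2 of 7), Otulin, which encodes a deubiquitinase of the NF-kB pathway, Tagap, Pip4k2a, Rnf19a and Bcor had 2 regions each. Called only without IL-18 were 3 of 12 regions of 4930459C07Rik (5 without IL-12 plus IL-18 replicate 2), 3 of 10 of Gm27162, 2 of 7 of Nfatc1, a transcription factor gene of calcium signalling, 2 of 4 of Icos, 2 of 6 of Ptprc and 2 of 6 of Il18r1. All CDK9 regions of Ifng, Socs1, Socs3, Pim1 and Cish were called in every library of both groups.

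The immediate early list's mean difference was 6.88 points against -4.21 in random lists (two-sided permutation across genes, adjusted p = 0.0163 over 13 lists), and no other list passed. T-cell marker genes had 0 regions called only with IL-18 and 2 called only without it of 10 (adjusted p = 0.102, and 0.0374 without IL-12 plus IL-18 replicate 2), and lymphocyte transcription factors 4 and 16 of 153 (adjusted p = 0.152). Ribosomal protein, cell cycle, glycolysis and polymerase pausing genes passed in none of the comparisons in which they were tested (lowest adjusted p = 0.517, 0.391, 0.416 and 0.416), and B-cell, myeloid and erythroid markers had fewer than 5 regions for DDX5, NELFE and CDK9 and were not tested. The immediate early call was lost on promoters alone (adjusted p = 0.294), with the widest region per gene (0.718) and without IL-12 replicate 2 (0.158). Of 1019 regions called in both unstimulated libraries and in exactly 2 of the 4 compared, 14.5% were called only with IL-18, 22.0% only without it and 63.5% were mixed, where chance gives 16.7%, 16.7% and 66.7% for equal rates and the rates of these libraries give 14.1%, 17.9% and 68.0%. Mean calls were 8053.5 and 8419, an exact two-sided permutation p of 1, and without IL-12 plus IL-18 replicate 1 the difference of -365.5 calls turned to 489. The counts of regions moved to between 467 and 778 called only with IL-18, and 590 and 1511 only without it, when 1 library was left out, most of all without IL-12 plus IL-18 replicates 1 and 2 respectively.

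Nearly all regions of the other proteins overlapped a STAT4 region, with 91.6% of DDX5, 96.0% of NELFE and 94.9% of CDK9 regions overlapping one, against 1.47%, 1.88% and 1.63% after shuffling. The shuffles spread positions over whole chromosomes and did not keep them at promoters, where regions of all antibodies gather. No control antibody or unstimulated STAT4 library is among the samples, so the overlap does not show a share particular to STAT4. All 66 IL-12-only DDX5 regions overlapped a STAT4 region. For CDK9, 877 of 884 IL-12-only regions (99.2%) and 1333 of 1625 unstimulated-only regions (82.0%) did, and CDK9 regions had fewer calls after IL-12 on average at both kinds of place, with a mean difference of -8.75 points with a STAT4 region and -60.8 without, 52.0 points apart (exact two-sided circular-shift p across regions = 8.93e-05, the smallest possible). The difference was 90.1 points for DDX5, 39.7 for CDK9 after IL-12 and IL-18 (-12.6 with and -52.4 without) and -12.3 for the IL-18 step. Once regions of like width were compared, the IL-18 step's value was -4.06. The circular-shift test beside it used differences centred within classes of like width, not this value itself, and still passed. For NELFE the difference was -14.5 points, and -11.2 at like width. The centred circular-shift test gave an exact p of 0.263 for NELFE and did not pass. NELFE regions overlapped CDK9 regions in 83.0% of cases, and CDK9 regions NELFE regions in 55.6%. Where a CDK9 region separated IL-12 from unstimulated libraries, it was IL-12-only in 49.3% of cases at IL-12-only NELFE places in 15.8% at NELFE places called without IL-12 and in 33.0% where there was no NELFE region. Of all CDK9 regions, 8.57%, 0.931% and 11.8% in these classes were IL-12-only. After IL-12 and IL-18 the shares of separating regions were 36.8%, 8.61% and 31.4%. CDK9 cells were taken later after IL-12 than cells of the other antibodies, and in smaller number per library. The overlaps and shares that involve CDK9 therefore set unlike times and inputs side by side. The CDK9 libraries also carried a batch label that no other antibody shared.

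**Figure D1:**
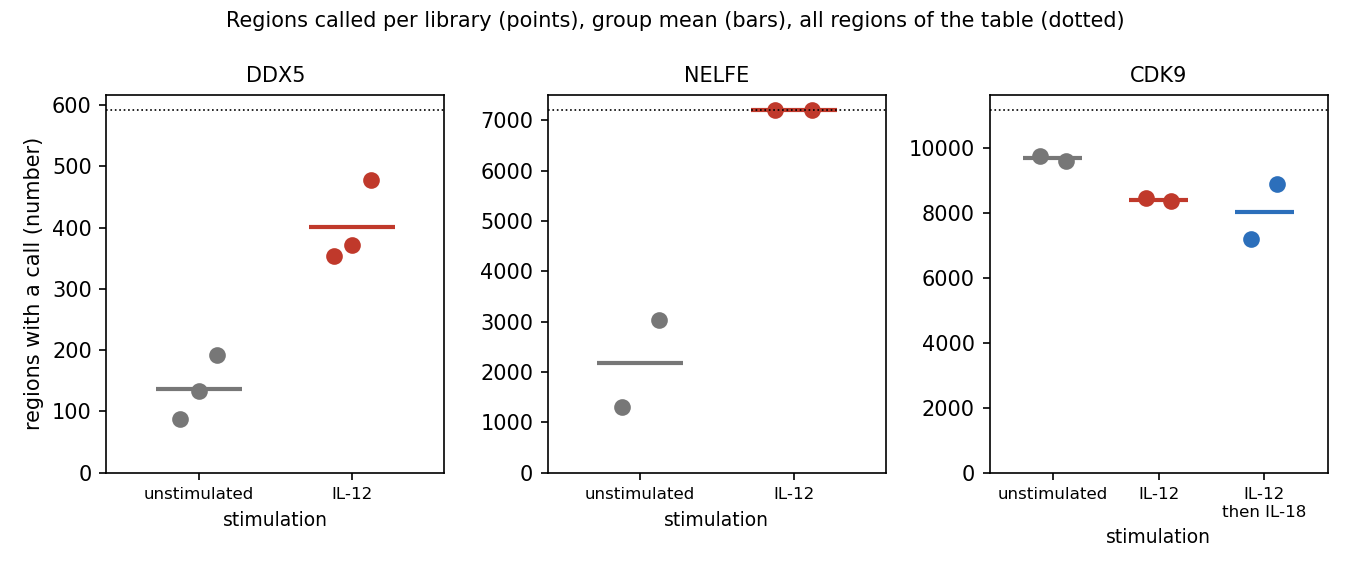
Regions with a call per library (y axis, number of regions) by stimulation for DDX5, NELFE and CDK9, with a point per library, a horizontal bar at the group mean and a dotted line at the number of regions in the table. DDX5 IL-12 libraries had 354 to 478 calls against 87 to 192 without IL-12, and CDK9 IL-12 libraries 8375 and 8463 against 9628 and 9760.

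**Figure D2:**
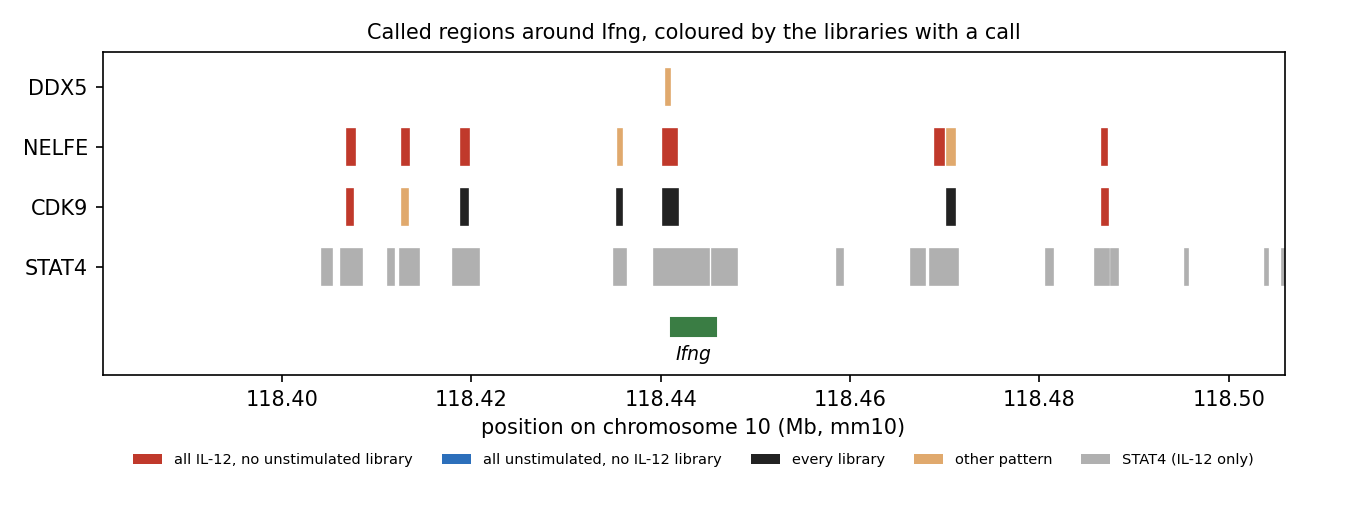
Map of called regions around Ifng on chromosome 10 (x axis, position in Mb, mm10; y axis, antibody), with IL-12-only regions in red, regions called in every unstimulated and IL-12 library in black, other patterns in orange and STAT4 in grey. NELFE was IL-12-only at the promoter and at 5 distal regions, and CDK9 at 2 distal regions, and no region there was unstimulated-only.

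**Figure D3:**
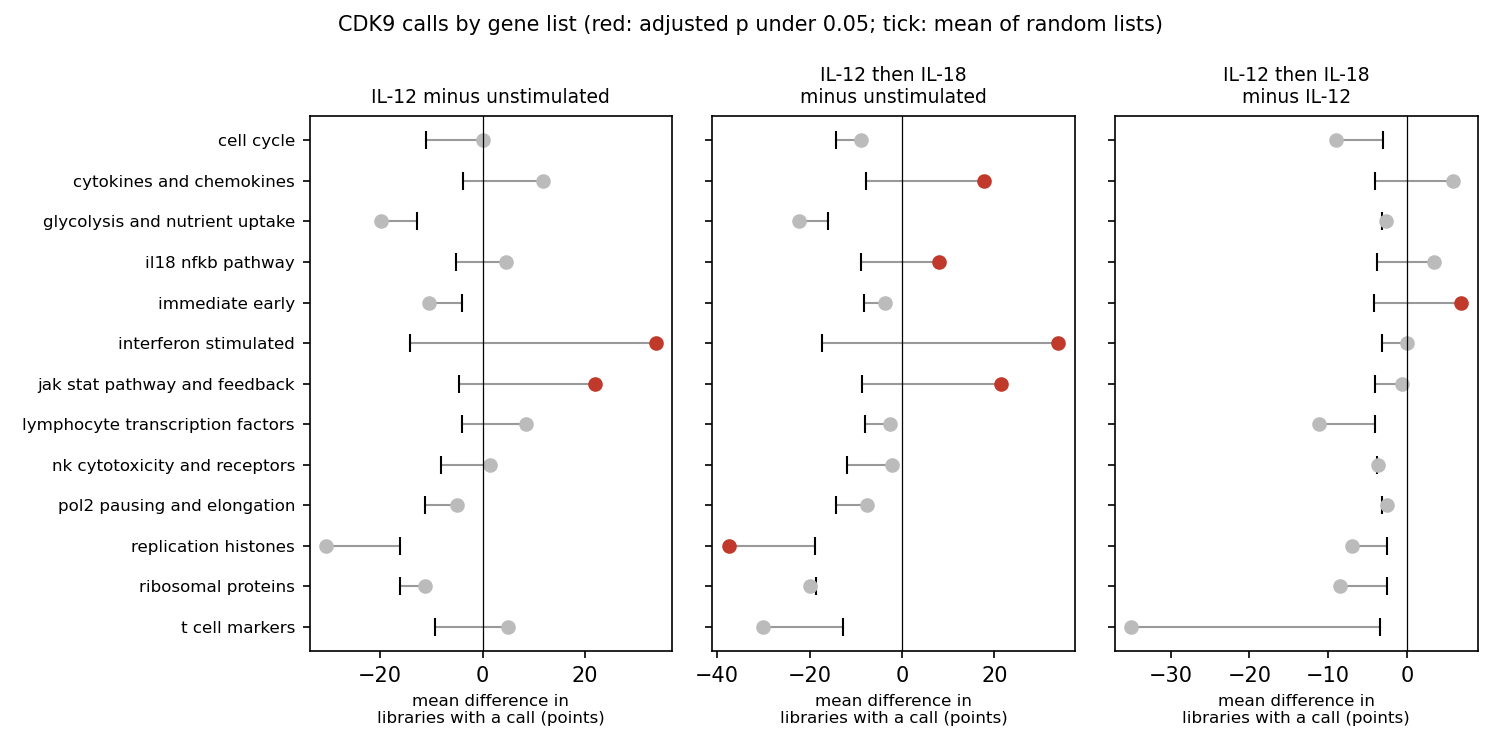
Mean difference in the share of CDK9 libraries with a call (x axis, percentage points) for each tested gene list (y axis) in the 3 CDK9 comparisons, with points in red where the adjusted p was under 0.05 and a tick at the mean of random lists. Interferon-stimulated genes stood at 33.8 points after IL-12 against -14.2 in random lists.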

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

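The tests of the interferon list, the DDX5 batches and the DDX5 splits were chosen after the result was seen, and both tests of the NELFE pattern before it. Calls per library went opposite ways between antibodies after IL-12, with a mean difference of 5037.5 for NELFE, 264 for DDX5 and -1275 for CDK9. Each library of the one group lay above or below each of the other. The differences between antibodies were not tested. CDK9 cells also had a further step in medium after IL-12, and fewer cells per library, so times and inputs were unlike between antibodies. DDX5, NELFE and CDK9 libraries also carried different batch labels, so antibody and batch cannot be told apart.

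NELFE was called in both IL-12 libraries and neither unstimulated library at 4056 regions, Ifng and Socs1 among them. That narrow regions make up this whole pattern is argued against by the widest 10%, of which 14.1% (95% interval 11.7 to 16.9, Clopper-Pearson, counting error alone) showed it. The share in the narrowest 10% was 86.4%, so most of the pattern lay at narrower regions. Width does not measure signal, so weak regions as the source stay open. Only 1 region had the reverse pattern, which carries little weight because the IL-12 libraries called 99.9% of all NELFE regions. Lower sensitivity of the unstimulated libraries, whose calls numbered 1314 and 3024, may explain the IL-12-only pattern instead. CDK9 regions that separated the groups were IL-12-only more often at IL-12-only NELFE places than at NELFE places called without IL-12, by a difference in share of 0.324 at like width, but the bound set for this test was too weak, since it measures CDK9 and not the amount of NELFE at the same places. CDK9 was also mapped at a later time after IL-12 than NELFE, with fewer cells per library and under another batch label. Weak detection without IL-12 and more NELFE after IL-12 cannot be told apart with calls alone.

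CDK9 gained calls at interferon-stimulated genes after IL-12. The Gbp and Irgm family clusters held 7 of the 12 IL-12-only regions, and without these families the other 22 regions of the list still lay 30.7 points above random lists (two-sided permutation p across genes = 0.00821), which argues against these clusters as the whole pattern. A single unstimulated library as its source is argued against by the lower value without either, 45.6 points above random lists. A response to IL-12 itself, or to interferon made in the culture, stays open as an untested hypothesis.

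For the IL-12-only regions of DDX5, the 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05: 2 of the 10 had as many regions, the real one with 66 (66 in one direction and 0 in the other) and the split by batch with 71 (30 and 41). Batch as the whole source is argued against by the batches alone, where mean calls after IL-12 were higher by 244 and 233, and regions called only after IL-12 outnumbered the reverse by 18 and 35.6 to 1, against 2.10 and 1.41 for equal rates within a batch. With 1 library in an arm of each batch, these ratios restate the calls per library. Whether binding or library yield changed was not tested.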

How the results depend on the processing

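Alternatives added after seeing the data are the group call, width-matched random lists, Fisher's test, width-standardised overlap, the wider 50% of each table, DDX5 without the regions that overlap no STAT4 region, and list and STAT4 results without single libraries. Not run, because they need counts, were other scaling factors, no filter, the DESeq2 test, an adjusted p under 0.1, a fold-change minimum, camera, and peaks by mean count (widest regions took their place). Whether replicate numbers pair the libraries is not settled. For DDX5 the same-numbered correlations were 0.188 and 0.210 within a batch and -0.129 across batches, so number and batch cannot be told apart. For NELFE they were 0.00, but its IL-12 libraries differed at only 9 regions, so this value says little. A replicate block cannot change counts of regions or mean differences (264 for DDX5), so it says nothing about stability. Among results without each library, 657 kept direction and side of the threshold or moved little, 44 moved, 7 weakened and 2 reversed, and for other alternatives 178 kept, 45 moved and 9 weakened, leaving out 26 values that could not change by construction (the replicate block, the compared libraries alone and each STAT4 library alone). Most of the values without each library, 564, were counts of regions at named genes, many chosen by these same counts. Such a count can only stay or rise when a library is left out. The number kept is therefore no measure of stability. The interferon and JAK-STAT lists passed for CDK9 after IL-12 without each library (41.0 to 55.0 and 23.8 to 29.5 points above random lists). Unless said otherwise, the cause was not tested.

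Counts of regions called in 1 group only rise by construction with fewer libraries. They were 234 higher and 13 lower for DDX5 in batch 1 and 178 and 5 in batch 2. By the group call they were 379 and 48 for DDX5, 10 lower for NELFE, 1428 and 3261 for CDK9 after IL-12, 1256 and 3691 after IL-12 and IL-18, and 1045 and 1647 for the IL-18 step. Without 1 library, DDX5 had 66 to 166 higher (most without IL-12 replicate 1) and 0 to 12 lower (12 without unstimulated replicate 3, 2 without IL-12 replicate 1), NELFE 1 to 6 lower (6 without IL-12 replicate 1, 5 without replicate 2), CDK9 after IL-12 1662 to 2492 lower (most without IL-12 replicate 1), after both cytokines 1788 to 3430 lower (most without IL-12 plus IL-18 replicate 2), and the IL-18 step 467 to 778 higher (778 without IL-12 plus IL-18 replicate 1, 693 and 735 without IL-12 replicates 1 and 2) and 590 to 1511 lower (1511 without IL-12 plus IL-18 replicate 2, 686 and 759 without IL-12 replicates 1 and 2). The difference in calls of the IL-18 step ranged from -1220 to 489 (the latter without IL-12 plus IL-18 replicate 1), and Il12rb2, with 1 region higher in that step, had more lower than higher ones without IL-12 replicate 1. Among 564 counts at named genes without 1 library, 25 moved by over 1.5 times, at 17 genes, among them Prex1 for NELFE and Pik3ap1 for CDK9 after both cytokines.

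For NELFE, 2 lists passed with promoter regions only, with 1 region per gene, and width-matched (the added ones being immediate early genes for the first 2 and JAK-STAT for the last). For CDK9 after both cytokines, 3 passed with promoter regions only and with Fisher's test, and 2 to 5 without 1 library (2 without IL-12 plus IL-18 replicate 1, 3 without unstimulated replicate 2). For the IL-18 step, 0 passed with promoter regions only and with 1 region per gene, 2 with Fisher's test, and 0 to 2 without 1 library (0 without IL-12 replicate 2, 2 without IL-12 plus IL-18 replicate 2). The lists added in that step were IL-18 and NF-kB genes with Fisher's exact test (adjusted p = 0.0368) and T-cell markers without IL-12 plus IL-18 replicate 2 (-43.7 points, adjusted permutation p = 0.0374). For CDK9 after IL-12, lymphocyte transcription factors passed with 1 region per gene (adjusted permutation p = 0.0484) and with Fisher's exact test (adjusted p = 0.000844), and histones width-matched (adjusted permutation p = 0.00312). Points above random lists (above all other regions for Fisher's test), after both cytokines, were 32.2 for cytokines on promoters and 12.3 with 1 region per gene, 13.3 for the IL-18 and NF-kB list width-matched and 5.93 with Fisher's test, and -17.1 for histones on promoters and -6.78 with Fisher's test. Without 1 library they were 22.2 to 28.8, 14.2 to 19.7 and -21.0 to -16.7. For immediate early genes in the IL-18 step they were 8.56 on promoters, 3.26 with 1 region per gene and 8.54 to 13.6 without 1 library.

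The NELFE difference at STAT4 regions was -11.2 points width-standardised, and the circular-shift test of differences centred within classes of like width did not pass. Without unstimulated replicate 2 the difference was -9.003, where it passed. Overlap with STAT4 in the wider 50% of each table was 94.6% for DDX5, 91.2% for NELFE and 85.0% for CDK9.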

Other observations

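The DDX5 regions without STAT4 overlap were singled out after the result was seen, and the test of shared places was set before it. A group of 50 DDX5 regions overlapped no STAT4 region and went the other way from the rest, with a mean difference of -38.0 points after IL-12 against 52.1 for the others. Within batches the values were -25 against 47.2 in batch 1 and -15 against 44.3 in batch 2. Of these, 38 were intergenic, 13 were assigned to the microRNA gene Mir101c and lay between positions 3003327 and 3033878 of chromosome 9, and the median width of the 50 was 233.5 bp against 440 bp. Mir101c also held 8 NELFE regions, 14 CDK9 regions and 1 STAT4 region. Of the 50 regions, 47 and 48 were called in the unstimulated libraries of batch 1 against 35 in its IL-12 library, and 18 in the unstimulated library of batch 2 against 15 and 6 in its IL-12 libraries. They made up 54.0% and 36.1% of all calls in the unstimulated libraries of batch 1, against 9.89% in its IL-12 library. In batch 2 they made up 9.38% without IL-12, against 4.03% and 1.26% with it. Chromosome Y held 5 of them. Whether these regions reflect binding of DDX5 was not tested.

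Genes with IL-12-only regions for DDX5, NELFE and CDK9 at once included Bcl2, a survival gene, Ppp1r3b and Tnfrsf9. At the level of places, all 66 IL-12-only DDX5 regions overlapped a NELFE and a CDK9 region, but 10 overlapped an IL-12-only NELFE region and 0 an IL-12-only CDK9 region. A hypothesis was that the 3 proteins gain calls at the same places more often than their separate rates give. Of the IL-12-only DDX5 regions, 0 overlapped an IL-12-only region of both other proteins, against a mean of 0.111 under circular shifts. Because 1 DDX5 region in all lay at such a place, the test leaves open whether the 3 antibodies gain calls at the same places no more often than their separate rates give. The comparison also sets unlike times, inputs and batch labels side by side. CDK9 cells were taken later after IL-12 than DDX5 and NELFE cells, and in smaller number per library.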
